A study of Homo sapiens with 12 samples.

How the data were processed

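RNA of T84 monolayers was hybridised to 12 Agilent whole human genome arrays of design 014850 with 1 dye, Cy3, from 0.2 µg of total RNA each. Per the file headers the authors scanned the arrays and extracted them with Feature Extraction 9.5.3.1. The deposited scanner files hold the processed signal, the mean signal and the local background of each spot as intensity on a linear scale. Per the file headers they also hold marks of another kind (unit other), namely whether a spot was well above background, an outlier or saturated. The deposited values of the series hold log2 values. Set against the scanner values, each of its columns is log2 of the processed signal minus the array's 75th percentile, with each probe centred on its median (r at least 0.9997 after the same centring). Its medians per array lay between -0.15 and 0.07. Whether the authors removed any spot before that step is not given in the sources used here.

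The values analysed were log2 of the processed signal minus its 75th percentile over the 43376 non-control spots of each array. The 1639 control spots and 137 outlier spots were left out, and spots of 1 probe were averaged, which gave 41000 probes. A probe was kept where it was well above background on all 3 arrays of at least 1 group (31071 probes). Of several probes with 1 gene name the one with the highest mean was used, which left 23353 genes, 14538 of them with a gene symbol. Names in the files are those of the array's design. They were updated through RefSeq gene records, for 23434 probes by accession, 2317 by symbol and 1043 by an older symbol, and 14206 probes have no symbol. Positions are those of the probes on build hg17, from the array files. Among named genes the probes of CREM and CYCS in the direct model, of TNFRSF10B, PFKFB3 and PDE4D in the indirect model, of SLC16A3 in the difference and of ITGA2B without neutrophils were called in opposite directions. Another probe was not called for DNAJA4 and HBA2 in the direct model, HBA2, ANO1, KLF2, NR4A1 and MT1E in the indirect model, KLF2 and NR4A1 in the difference and HSD3B1, KLF2, HBA2, TNFRSF10B and CD55 without neutrophils.

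A group that was not well above background on any of its 3 arrays has only a bound. Its mean was then taken from, per array, the higher of the lowest signal among probes well above background and the probe's own, and the change is given as at least that many fold. All other folds are 2 to the power of the fitted log2 change.

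The 4 groups were formed from the labels, by model and by neutrophils, with 3 arrays each. All 12 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a mean per group and 8 residual degrees of freedom. The contrasts were neutrophils in the direct model, neutrophils in the indirect model, the difference between these effects, and the models without neutrophils. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast and called at 0.05. These contrasts, the gene lists, the rule for named genes and the other ways of processing were fixed before the data were examined. The contrast of both models with neutrophils was added after the headers had shown the scan days. The replicate numbers were not used as pairs.

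The 23 gene lists cover hypoxia, glycolysis, barrier genes, cytokines, immediate early genes, EGFR and cAMP signalling, NRF2, metallothioneins, heat shock, the unfolded protein response, p53, interferon, cholesterol, the cell cycle, the respiratory chain, junctions, mucins, ion transport and markers of epithelium, neutrophils and other blood cells. Some genes stand in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 23 lists of a contrast, and also with an estimated correlation and with fry. With arrays left out or with other processing, lists were tested at the preset correlation only. Named genes are those with a symbol that, in each neutrophil contrast, have the 15 highest and 10 lowest changes among called genes whose 3 arrays do not overlap the other 3. They are also the 6 highest and 6 lowest of each other contrast, without the overlap condition for the difference, up to 4 members of each list with the largest called change, and the 4 largest changes of like and of opposite sign in both models. XIST and genes of the Y chromosome were left out of this rule, and some genes that it gives are not reported here.

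The other ways were normexp background correction with an offset of 50, quantile normalisation, median centring, no filter on dim probes, only probes well above background on all 12 arrays, averaging the probes of a gene, the deposited log2 values, only the groups of the contrast in the fit, a trended robust prior, the replicate number as a block, an adjusted p under 0.01, and each array left out in turn. A fit with slide or scan day as a block could not be made, since no batch holds arrays with and without neutrophils. The steps were checked on simulated data with known changes in 23353 genes. At a log2 change of 2 the fit found 93.9% to 100.0% of the changed genes of each contrast, at 1 it found 71.6% to 91.0%, and at 0.5 it found 32.8% to 50.7%, with 7 to 13 false calls. Only 66 or 67 genes were changed at each size, while 40.9% to 65.2% of genes were called in the planned contrasts of the data. The shares found and the number of false calls therefore do not carry over to the data. No null list of 20 was called in any contrast. The simulated genes were independent of each other, while the estimated correlation within the lists reached 0.97 (metallothioneins). The simulation therefore does not check for false calls of lists whose genes are correlated. What signal over background limits is the fold of genes that are dim in a group.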

Results

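Gene expression was measured in T84 cells, a human intestinal epithelial line that grows as tight polarised monolayers on porous supports. All cultures carried 1 µM fMLP, a bacterial peptide that attracts neutrophils, on the apical side. In the direct model, neutrophils from venous blood migrated through the monolayer, and RNA was taken 2 h later. In the indirect model, naive monolayers received for 2 h the filtered supernatant of such a migration. Each model was run with and without neutrophils, which gives 4 groups of 3 arrays. The series asks how neutrophils in transit change the epithelial transcriptome. Earlier work on this process is concerned with hypoxia and its transcription factor HIF-1, which is background here. Between 72.6% and 78.7% of the spots were well above background on each array. The 75th percentile of the processed signal lay between 723 and 1318 intensity units, and 0 spots were saturated. The median SD between the 3 arrays of a group was 0.12 on the log2 scale, against 0.06 between spots of 1 probe within an array, and 12 arrays limit the precision. The labels do not say whether replicates were separate cultures or separate blood donations, so p-values measure only the spread between these samples, which may be technical. The array headers give 2 scan days and 4 slides. Every array with neutrophils was scanned on 1 day and every array without them on the other, and each group has a slide of its own. Scan day and slide therefore cannot be told apart from neutrophils in either model.

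The direct model asks how the RNA of the cultures differed once neutrophils had migrated through the epithelium. Neutrophils left in the cultures may add RNA of their own, which was not told apart from that of the epithelial cells. The highest change was in SRGN, the core protein of serglycin in storage granules, which was at least 61.0-fold higher (log2 8.01 ± 1.36 SE, adjusted p = 0.000465). The chemokine receptor CXCR4 was at least 35.3-fold higher, and S100A9, a subunit of calprotectin, at least 11.1-fold. The lowest changes were in genes that the epithelial cells themselves had expressed. PTCHD1 was at least 25-fold lower (log2 -6.66 ± 0.16, adjusted p = 6.67e-10), and the cancer-testis antigen MAGEA12 20.4-fold lower (log2 -4.35 ± 0.09, n = 3 and 3 arrays).

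Of the 23353 genes tested, 6876 were higher and 6711 lower with neutrophils in the direct model at an adjusted p under 0.05. With a log2 change of at least 1 as well, 1364 were higher and 1044 lower. The share of called genes that were higher was 50.6%, 44.5% with median centring and 59.9% with normexp fitted without control spots. Without direct replicate 1 with neutrophils, which stood apart in its neutrophil transcripts, 6165 were higher and 6622 lower, and 12210 genes were called in the same direction with and without it. Among genes whose arrays did not overlap between the groups, the others of the 15 highest were FCGR3A, PREX1, RASSF2, MGMT, CD53, THBD, GPR65, TNFAIP6, HCAR3, FPR1, HBB and MT1F. The FCGR3A transcript is close in sequence to that of FCGR3B. MGMT, which repairs alkylated guanine in DNA, had a small error (log2 4.60 ± 0.21, at least 21.0-fold). Besides PTCHD1 and MAGEA12, the 10 lowest were MAGEA1, PGAP4, TSPAN7, MMP10, CSAG2, MAGEA4, SGCE and NHS. MAGEA1 was at least 9.64-fold lower and TSPAN7 at least 23.5-fold lower, and CSAG2 and MAGEA4 were 24.5-fold and 24.2-fold lower. On build hg17 the PTCHD1 probe lies on chromosome X from 23171909 to 23171968, and the MAGEA12 probe on chromosome X from 151570480 to 151570539. The MGMT probe spans 131396272 to 131447489 on chromosome 10, and the SRGN probe lies on chromosome 10 from 70533839 to 70533898. In each of these named genes all 3 arrays with neutrophils lay above, or all below, the 3 without.

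Of 36 neutrophil markers measured, 24 rose and 4 fell in the direct model (median log2 change 2.21, adjusted p = 0.00104, and adjusted p = 0.694 with an estimated correlation). S100A8 rose by 6.51 ± 1.53 on the log2 scale and FCGR3A at least 23.4-fold. The arrays of this group were unlike each other. The median marker level relative to the array's 75th percentile was -4.42 in replicate 1, -0.66 in replicate 2 and -1.36 in replicate 3, against -4.77 to -4.22 in the 3 arrays without neutrophils. Replicate 1 had 26 of the 36 markers well above background, while replicates 2 and 3 had all 36. The arrays without neutrophils had 22 to 27. Without replicate 1 the median change of the markers was 3.02 (adjusted p = 2.62e-12 at the preset correlation). An estimated correlation, which was 0.70 for this list in the full fit, was not used without that array. Of 13 erythrocyte and platelet markers 5 rose and 3 fell (adjusted p = 0.447), with the haemoglobin chain HBB up by 3.95 ± 0.75 and HBA2 by 1.30 ± 0.15. Of 13 markers of lymphocytes, monocytes and eosinophils 2 rose and 3 fell (adjusted p = 0.934). Of 20 intestinal epithelial markers 7 rose and 11 fell (adjusted p = 0.287), with AGR2 higher by 0.96 ± 0.09 and CEACAM6 2.00-fold lower.

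Cell cycle genes were lower as a group. Of 27 measured, 0 rose and 26 fell in the direct model (median log2 -1.01, adjusted p = 1.12e-10, and adjusted p = 0.200 with an estimated correlation). The replication licensing factors MCM2 and MCM5 were 3.49-fold and 3.39-fold lower, and TYMS, which makes thymidylate, was 3.12-fold lower. Of 26 interferon-stimulated genes 19 fell and 3 rose (median -0.65, adjusted p = 0.00103, and adjusted p = 0.694 with an estimated correlation). The antiviral synthetase gene OAS3 was 3.46-fold lower and IFI6 2.77-fold lower. Of 22 genes of cholesterol synthesis 16 fell and 1 rose (median -0.43, adjusted p = 0.000227, and adjusted p = 0.694 with an estimated correlation). MVD was 2.92-fold lower. The median level of the cell cycle list was 0.78, 0.92 and 0.76 in replicates 1 to 3, against 1.25 to 1.33 without neutrophils, and replicate 1 had the lowest neutrophil marker level.

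All 10 metallothionein and zinc response genes rose in the direct model (median log2 3.04, adjusted p = 4.76e-05, and adjusted p = 0.694 with an estimated correlation). MT1F, a metal-binding protein gene, rose 14.3-fold and MT1M 10.7-fold. Their median level was 4.72 in replicate 1, which had the lowest neutrophil marker level, and 3.27 and 3.13 in replicates 2 and 3. Without neutrophils replicate 1 was also the highest (1.42, 0.61 and 0.30). Of 26 targets of the unfolded protein response and of ATF4, 19 rose and 4 fell (median 0.61, adjusted p = 0.00234, and adjusted p = 0.115 with an estimated correlation). The stress-induced NUPR1 rose 2.87-fold and the chaperone gene DNAJB9 2.45-fold, while the serine synthesis gene PHGDH fell 2.75-fold. With normexp the call for the unfolded protein response list ended (adjusted p = 0.289).

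Of 33 HIF-1 and hypoxia targets outside glycolysis 18 rose and 7 fell in the direct model (median 0.42, adjusted p = 0.0341, and adjusted p = 0.694 with an estimated correlation). The collagen-modifying enzyme genes PLOD2 and P4HA1 rose 4.57-fold and 3.14-fold, the oxygen sensor gene EGLN1 2.61-fold and ANKRD37 2.54-fold. The list test was no longer past the threshold without direct replicate 3 with neutrophils (adjusted p = 0.0557) or without direct replicate 2 lacking them (adjusted p = 0.0700). It also ended with normexp (adjusted p = 0.298), with normexp fitted without control spots (adjusted p = 0.0791) and with only the 2 groups in the fit (adjusted p = 0.0655). Of 17 p53 targets 10 rose and 1 fell (median 0.41, adjusted p = 0.0440, and adjusted p = 0.460 with an estimated correlation). The kinase gene PLK3 and the cell cycle inhibitor gene CDKN1A rose 2.51-fold and 2.43-fold. That call ended without the same 2 arrays (adjusted p = 0.0557 and 0.0809) and without indirect replicate 1 lacking neutrophils (adjusted p = 0.0569). Normexp with and without control spots (adjusted p = 0.0706 and 0.0584), quantile normalisation (adjusted p = 0.0696) and a fit of only the 2 groups (adjusted p = 0.0579) ended it for p53 targets too. The median level of p53 targets was -0.03 in replicate 1, with its low neutrophil marker level, and 0.26 and 0.28 in replicates 2 and 3, against -0.74 to -0.55 without neutrophils. That of HIF-1 targets was 1.57, 1.53 and 1.49 in the same order, against 0.99 to 1.33 without neutrophils.

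Immediate early genes, which respond to stimulation within minutes, also moved in the direct model: 20 of 37 rose and 2 fell (median 0.49, adjusted p = 0.0106, and adjusted p = 0.694 with an estimated correlation). EGR2 rose 4.14-fold, ID1 3.44-fold and FOS 2.89-fold. The mean level of the list was 0.85 in replicate 1, with its low neutrophil marker level, and 1.52 and 1.36 in replicates 2 and 3, against 0.87, 0.57 and 0.81 without neutrophils. Its median levels overlapped, 0.94 to 1.26 with and 0.73 to 1.32 without neutrophils. The call for this list ended with normexp (adjusted p = 0.298) and with normexp fitted without control spots (adjusted p = 0.0584). Of 14 targets of cAMP and CREB 5 rose and 2 fell (adjusted p = 0.287), with RGS2 up 5.16-fold, and without replicate 1 this list passed the test (median 0.56, adjusted p = 0.0173). Of 39 NF-kB and cytokine genes 5 rose and 6 fell (adjusted p = 0.934), with ICAM1 2.83-fold higher. Their median level was -1.37 in replicate 1 and 0.71 and -0.07 in replicates 2 and 3, against -0.11, -1.09 and 0.11 without neutrophils.

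The remaining 9 lists did not pass the test in the direct model. Of 20 EGFR ligands and MAPK feedback genes 6 rose and 5 fell (adjusted p = 0.911), with HBEGF 2.75-fold higher and TGFA 2.03-fold lower. Of 26 genes of mucins, trefoil peptides and antimicrobial proteins 13 rose and 5 fell (adjusted p = 0.129). In it the superoxide-generating oxidase NOX1 rose 11.4-fold and the trefoil peptide TFF3 5.98-fold, and REG4 was 5.96-fold lower. Of 10 barrier-protective HIF genes 5 rose and 2 fell (adjusted p = 0.545), with TFF1 3.04-fold higher. Of 22 genes of chloride secretion and ion transport 5 rose and 9 fell (adjusted p = 0.406). The chloride channel ANO1 was 7.61-fold lower and the anion exchanger SLC26A3 4.37-fold lower. Of 22 heat shock genes 7 rose and 6 fell (adjusted p = 0.926), with the co-chaperone DNAJA4 5.48-fold higher. Of 28 NRF2 targets 11 rose and 9 fell (adjusted p = 0.926), with SRXN1 higher by 1.00 ± 0.07. Of 24 glycolysis genes 9 rose and 6 fell (adjusted p = 0.926), with PKM at log2 -0.58 ± 0.09. Of 26 apical junction genes 9 rose and 4 fell (adjusted p = 0.447), with OCLN 1.69-fold higher. Of 25 nuclear genes of the respiratory chain 5 rose and 6 fell (adjusted p = 0.934), with SDHA 1.58-fold lower.

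Adjusted over the list alone, the direct counts were the same for all lists but 7. They were 5 higher and 5 lower for NF-kB and cytokine genes, 13 and 10 for NRF2 targets, 19 and 5 for unfolded protein response and ATF4 targets, and 4 and 19 for interferon-stimulated genes. They were 5 and 4 for the respiratory chain, 25 and 4 for neutrophil markers, and 1 and 3 for lymphocyte, monocyte and eosinophil markers. The signs of median, mean and tests did not match for NF-kB and cytokine genes, EGFR ligands and MAPK feedback, the respiratory chain and lymphocyte, monocyte and eosinophil markers, none of which passed. No list call in the direct model held with an estimated correlation.

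**Figure D1:**
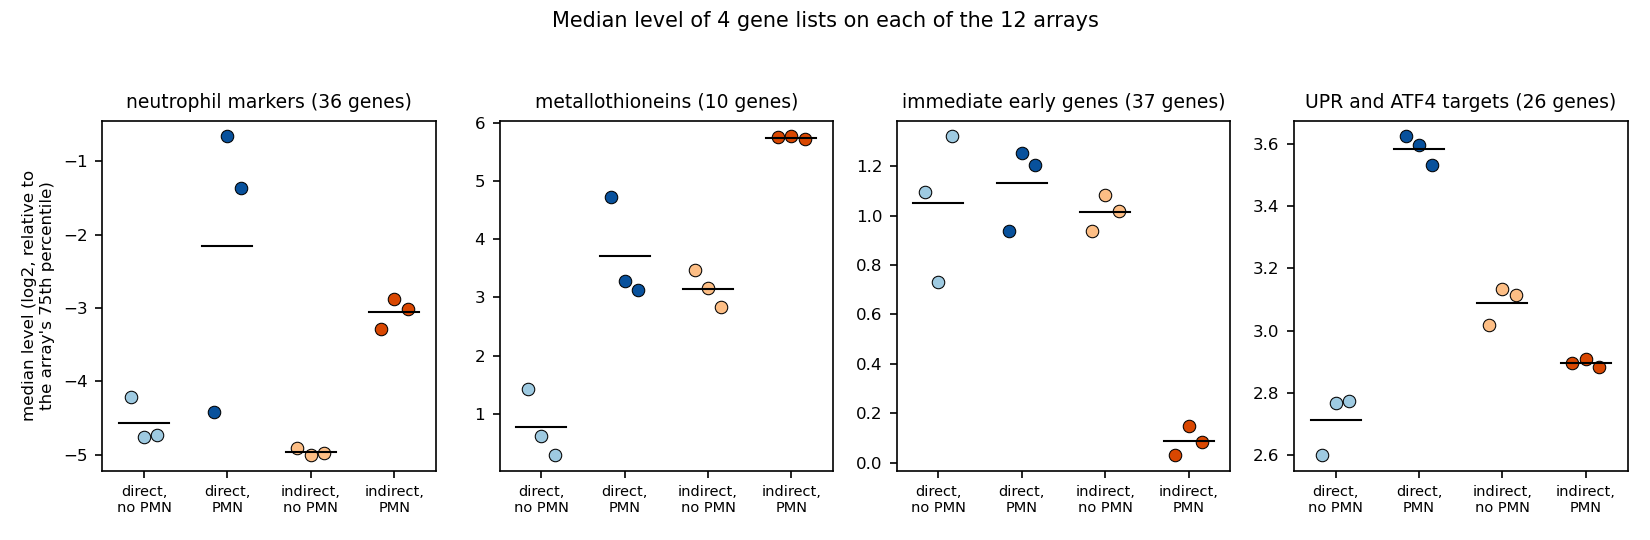
Median level of 4 gene lists on each of the 12 arrays, in log2 units relative to the array's 75th percentile; points are arrays and lines are means of the 3 arrays of a group. Neutrophil markers sit at -4.42 in direct replicate 1 with neutrophils against -0.66 and -1.36 in replicates 2 and 3, and between -3.28 and -2.87 in the indirect arrays with neutrophils.

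The indirect model asks how the RNA of naive cultures differed after they received the cell-free products of a migration. RNA of neutrophils may be present in these cultures too, and it was not told apart from that of the epithelial cells. The highest change was in CXCR4, at least 99.8-fold higher (log2 8.30 ± 1.47, adjusted p = 0.000479, n = 3 and 3 arrays), and SRGN was at least 52.2-fold higher. MGMT was at least 27.2-fold higher (log2 6.14 ± 0.21). The lowest were the matrix metalloproteinase gene MMP10, 36.3-fold lower (log2 -5.18 ± 0.29), and PTCHD1, at least 9.57-fold lower. Unfolded protein response and ATF4 targets fell as a group (adjusted p = 8.56e-06, and adjusted p = 0.0152 with an estimated correlation).

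In the indirect model 9468 genes were higher and 5768 lower, of which 2139 and 1311 had a log2 change of at least 1. The median over all genes was 0.17 with the main scaling, 0.06 with quantile normalisation and 0.02 with each array centred on its median, so the share of called genes that were higher depends on the scaling. It was 62.1%, 53.7% and 49.7% in that order, and 71.6% (12516 higher and 4968 lower) with normexp fitted without control spots, which was chosen after seeing the data. List tests compare a list with all other genes and so are relative to this shift. Among genes whose arrays did not overlap between the groups, the others of the 15 highest were AQP9, S100A8, FCGR3A, STK33, PREX1, NFE2, CD53, LCP2, ZNF114, CLEC4E, FGR and USP51. The transcription factor gene NFE2 was at least 24.9-fold higher and the kinase gene STK33 at least 7.50-fold. Besides MMP10 and PTCHD1, the 10 lowest were TSPAN7, MAGEA1, CSAG2, NHS, CCL20, CSAG1, BLNK and SGCE. CCL20, a chemokine that draws lymphocytes and dendritic cells, was 16.1-fold lower (log2 -4.01 ± 0.62).

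Of 36 neutrophil markers 21 rose and 2 fell in the indirect model (median 1.96, adjusted p = 0.0293, and adjusted p = 0.881 with an estimated correlation). S100A8 was at least 20.3-fold higher and the water channel AQP9 at least 21.0-fold. The median marker level was -3.28, -2.87 and -3.01 in the arrays with neutrophils and -5.00 to -4.90 in those without. All 36 markers were well above background on each array with neutrophils, and 23 to 25 on those without. Probes were kept only where all 3 arrays of at least 1 group were well above background. The count of 36 is therefore partly set by that filter. The list test missed the threshold without indirect replicate 2 with neutrophils (adjusted p = 0.0547) and without indirect replicates 1 or 2 lacking them (adjusted p = 0.0756 and 0.0606). Without direct replicate 1 with neutrophils, which enters the shared estimate of spread, its adjusted p was 1.42e-05 at the preset correlation. The call for neutrophil markers also ended with normexp fitted without control spots (adjusted p = 0.110) and with only probes well above background on all 12 arrays (adjusted p = 0.211). Of 13 erythrocyte and platelet markers 9 rose and 1 fell (adjusted p = 0.0849), with HBB higher by 3.91 ± 0.75 on the log2 scale. Of 13 markers of lymphocytes, monocytes and eosinophils 5 rose and 0 fell (adjusted p = 0.612), with NKG7 2.15-fold higher. Of 20 intestinal epithelial markers 10 rose and 6 fell (adjusted p = 0.871), with FABP1 2.02-fold higher and CEACAM5 2.37-fold lower.

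In the indirect model 26 of 37 immediate early genes fell and 3 rose (median -0.81, adjusted p = 2.36e-07, and adjusted p = 0.423 with an estimated correlation). KLF2, NR4A1 and EGR1 were 11.8-fold, 7.24-fold and 5.10-fold lower, while a second probe each of KLF2 (log2 0.01) and NR4A1 (-0.04) was not called. Of 20 EGFR ligands and MAPK feedback genes 17 fell and 1 rose (median -1.04, adjusted p = 2.36e-07, and adjusted p = 0.278 with an estimated correlation). The growth factor gene HBEGF was 6.89-fold lower and the feedback inhibitor gene SPRY4 3.48-fold lower. Of 39 NF-kB and cytokine genes 20 fell and 5 rose (median -0.70, adjusted p = 0.00217, and adjusted p = 0.710 with an estimated correlation). The interferon-induced chemokine gene CXCL10 was 11.8-fold lower and RELB 5.45-fold lower. Of 14 targets of cAMP and CREB 6 fell and 1 rose (median -0.34, adjusted p = 0.0211, and adjusted p = 0.432 with an estimated correlation), with the clock gene PER1 4.71-fold lower. Of 26 interferon-stimulated genes 23 fell and 1 rose (median -1.40, adjusted p = 1.28e-10, and adjusted p = 0.347 with an estimated correlation). IFIT1 and IFI44L were 5.16-fold and 4.08-fold lower. Neutrophil markers had a median level of -3.28 to -2.87 on these arrays with neutrophils and of -5.00 to -4.90 on those without.

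Stress genes moved in different directions in the indirect model. Of 26 unfolded protein response and ATF4 targets 19 fell and 7 rose (median -1.05, adjusted p = 8.56e-06), and this call held with an estimated correlation (adjusted p = 0.0152). The median level of the list differed less, 2.88 to 2.91 on arrays with and 3.02 to 3.13 on those without neutrophils. Its mean level was 2.47 to 2.50 with and 3.29 to 3.33 without them. The phosphatase regulator PPP1R15A was 6.09-fold lower, PHGDH 5.88-fold and SESN2 5.73-fold. Of 17 p53 targets 8 fell and 1 rose (median -0.28, adjusted p = 0.0144, and adjusted p = 0.278 with an estimated correlation), with the growth arrest gene GADD45A 3.30-fold lower. Of 22 heat shock genes 16 rose and 3 fell (median 0.58, adjusted p = 0.0124, and adjusted p = 0.512 with an estimated correlation). DNAJA4 rose 9.82-fold and the inducible chaperone gene HSPA1A 3.24-fold, with probes of HSPA1A between log2 1.65 and 5.98 and of DNAJA4 between 0.58 and 3.30. All 10 metallothionein and zinc response genes rose (median 2.63, adjusted p = 0.00200, and adjusted p = 0.512 with an estimated correlation), MT1F 13.1-fold. Of 28 NRF2 targets 12 rose and 9 fell (adjusted p = 0.909), with the haem-degrading HMOX1 4.00-fold higher and the cystine transporter SLC7A11 4.27-fold lower. The median neutrophil marker level of -3.28 to -2.87 on the indirect arrays with neutrophils goes with these changes too.

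Cell cycle genes were lower here too, with 17 of 27 fallen and 5 risen in the indirect model (median -0.69, adjusted p = 0.000152, and adjusted p = 0.423 with an estimated correlation). The mitotic kinase AURKB was 3.64-fold lower and FOXM1 2.69-fold lower. Of 26 apical junction genes 17 fell and 4 rose (median -0.58, adjusted p = 0.000403, and adjusted p = 0.423 with an estimated correlation). The pore-forming claudin CLDN2 rose 6.71-fold, while JUP and TJP3 were 2.22-fold and 2.14-fold lower. On the same arrays neutrophil markers had a median change of 1.96. The other lists did not pass. Of 33 HIF-1 and hypoxia targets 17 rose and 10 fell (adjusted p = 0.818), with ANGPTL4 5.82-fold and ANKRD37 5.33-fold higher and MAFF 4.87-fold lower. Of 24 glycolysis genes 14 rose and 4 fell (adjusted p = 0.220), with PGAM1 2.20-fold higher. Of 10 barrier-protective HIF genes 5 rose and 4 fell (adjusted p = 0.740), with CD55 2.34-fold lower. Of 26 genes of mucins, trefoil peptides and antimicrobial proteins 11 rose and 7 fell (adjusted p = 0.859), with NOX1 7.85-fold and TFF3 5.92-fold higher. Of 22 genes of chloride secretion and ion transport 8 rose and 10 fell (adjusted p = 0.289), with ANO1 6.59-fold lower. Of 22 cholesterol synthesis genes 10 rose and 4 fell (adjusted p = 0.740). Of 25 respiratory chain genes 6 rose and 5 fell (adjusted p = 0.871), with SDHA 1.63-fold lower.

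Adjusted over the list alone, the indirect counts were the same for all lists but 3. They were 3 higher and 27 lower for immediate early genes, 0 and 4 for cAMP and CREB targets, and 5 and 17 for apical junctions. The set test gave the opposite sign to the median for barrier-protective HIF genes, NRF2 targets, the respiratory chain and epithelial markers, none of which passed. Only the unfolded protein response and ATF4 list held in the indirect model with an estimated correlation.

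**Figure D2:**
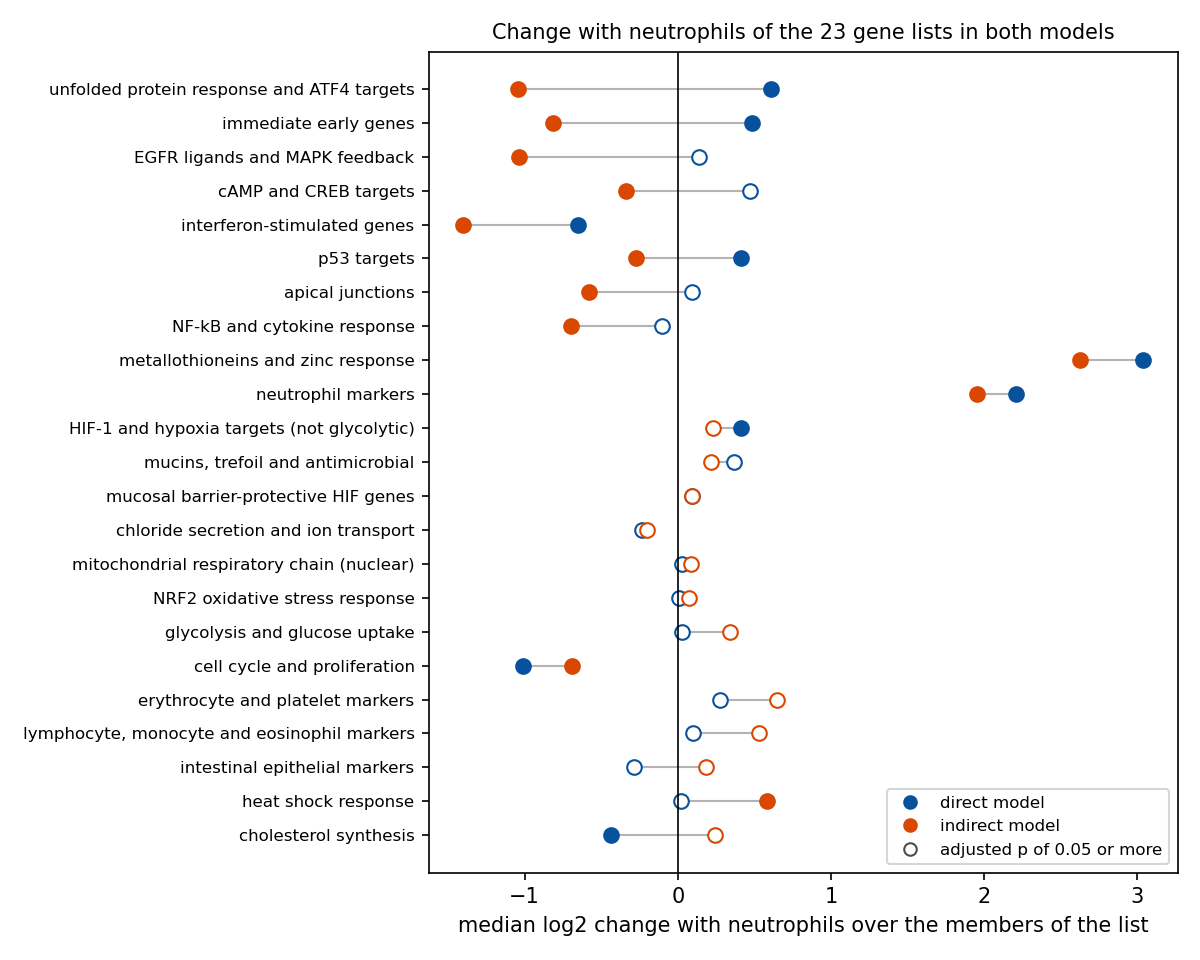
Median log2 change with neutrophils over the members of each of the 23 gene lists, in the direct model (blue) and the indirect model (orange), with filled points for an adjusted p under 0.05 in the list test. Unfolded protein response and ATF4 targets had a median of 0.61 in the direct and -1.05 in the indirect model, and metallothioneins 3.04 and 2.63.

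Here the changes of the direct and the indirect model are set side by side, gene by gene. Across the 23353 genes, which are not independent replicates, the 2 log2 changes correlated (Pearson's r = 0.587, Spearman's rho = 0.467). In all, 4523 genes were higher in both models against 2788 by independence, and 3185 were lower in both against 1658. Another 717 were higher in the direct and lower in the indirect model, and 1421 the reverse. With a log2 change of at least 1 in both, 1133 genes moved the same way and 38 in opposite ways. The largest changes of opposite sign were in EGR2 (log2 2.05 ± 0.29 direct and -2.22 ± 0.29 indirect), FOS (1.53 ± 0.27 and -1.81 ± 0.27), HBEGF (1.46 ± 0.16 and -2.78 ± 0.16) and the intestinal transcription factor gene ISX (1.45 ± 0.11 and -1.51 ± 0.11).

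The test of the difference itself, the change with neutrophils in the direct minus that in the indirect model, called 3788 genes with a higher and 6595 with a lower effect in the direct model. A difference of at least 1 was seen in 1032 and 1795 of them. The excess of lower effects depends on the scaling: the counts were 4505 and 5469 with median centring, 4481 and 5821 with quantile normalisation, and 3534 and 7194 with normexp fitted without control spots. With normexp as planned they were 1664 and 2097. Because arrays with and without neutrophils enter on both sides, a shift between scan days that is the same in both models cancels here, but slides do not. The highest were EGR2 (4.27 ± 0.40), HBEGF (4.24 ± 0.23), JDP2, KLF2 (a second probe at -0.27, not called), SESN2 and FOS, and the lowest CYP1A1 (-3.66 ± 0.19), RNF182, AKAP7, GRIA3, STK33 and HAS1. CYP1A1 is an enzyme induced through the aryl hydrocarbon receptor. GRIA3 missed the threshold without direct replicate 3 with neutrophils (log2 -2.98, adjusted p = 0.0559), without direct replicate 1 lacking them (-2.99, adjusted p = 0.0542) or without indirect replicate 2 lacking them (-2.97, adjusted p = 0.0585). With normexp RNF182 (0.10) and HAS1 (0.0616) turned positive and were not called. No bound was formed for differences between the effects, which are fitted values also where a gene was dim. GRIA3 and STK33 were not well above background on any array of at least 1 group. On build hg17 the probe of EGR2 lies on chromosome 10 from 64241856 to 64241915, that of HBEGF on chromosome 5 from 139693236 to 139693295, and that of CYP1A1 on chromosome 15 from 72799615 to 72799674.

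Of the 26 unfolded protein response and ATF4 targets 20 had a higher and 0 a lower effect in the direct model (median difference 1.13, adjusted p = 5.55e-15), which held with an estimated correlation (adjusted p = 0.000370). SESN2 differed by 3.40 ± 0.17 and NUPR1 by 2.51 ± 0.16. So did the p53 targets, 11 higher and 1 lower of 17 (0.91, adjusted p = 6.55e-06, and adjusted p = 0.0263 with an estimated correlation), with TNFRSF10B at 1.71 ± 0.18. The other calls did not hold with it. Immediate early genes were 29 higher and 3 lower of 37 (1.45, adjusted p = 4.62e-12, and adjusted p = 0.251 with an estimated correlation), with ATF3 at 2.98 ± 0.24. EGFR ligands and MAPK feedback were 13 and 2 of 20 (1.15, adjusted p = 4.24e-07, and adjusted p = 0.238 with an estimated correlation). Interferon-stimulated genes were 17 and 1 of 26 (0.66, adjusted p = 1.56e-06, and adjusted p = 0.421 with an estimated correlation). Apical junctions were 16 and 1 of 26 (0.47, adjusted p = 6.12e-06, and adjusted p = 0.238 with an estimated correlation), though CLDN2 differed by -2.04 ± 0.30. cAMP and CREB targets were 8 and 0 of 14 (1.15, adjusted p = 0.000293, and adjusted p = 0.238 with an estimated correlation). NF-kB and cytokine genes were 12 and 4 of 39 (0.79, adjusted p = 0.00146, and adjusted p = 0.647 with an estimated correlation). Part of some of these differences lies between the controls. Direct minus indirect cultures had a median of -0.45 without and 0.69 with neutrophils for unfolded protein response and ATF4 targets. For interferon-stimulated genes it was -0.31 without and 0.36 with them.

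Cholesterol synthesis was lower in the difference, 1 higher and 17 lower of 22 (-0.74, adjusted p = 0.000259, and adjusted p = 0.421 with an estimated correlation). Much of this lies between the controls. Direct minus indirect cultures had a list median of 0.52 without neutrophils, and of -0.22 with them, which did not pass the list test (adjusted p = 0.0933). Heat shock genes were 2 higher and 12 lower of 22 (-0.52, adjusted p = 0.00600, and adjusted p = 0.534 with an estimated correlation). Cell cycle genes were 2 and 13 of 27 (-0.36, adjusted p = 0.0223, and adjusted p = 0.534 with an estimated correlation). The cell cycle call ended without direct replicate 2 lacking neutrophils (adjusted p = 0.0530) and without indirect replicate 1 lacking them (adjusted p = 0.0580). HIF-1 and hypoxia targets were 15 and 10 of 33 (0.35, adjusted p = 0.0372, and adjusted p = 0.613 with an estimated correlation), with VEGFA at 1.57 ± 0.17 and EGLN3 at -2.24 ± 0.19. That call ended without direct replicate 3 with neutrophils (adjusted p = 0.0529), direct replicate 2 lacking them (adjusted p = 0.0742) or indirect replicate 3 with them (adjusted p = 0.0632). Normexp (adjusted p = 0.392), quantile normalisation (adjusted p = 0.0762) and median centring (adjusted p = 0.0562) ended it as well.

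Lists that did not pass the test of the difference were barrier-protective HIF genes (4 higher and 1 lower of 10, adjusted p = 0.0651), mucins (3 and 3 of 26, 0.145), metallothioneins (1 and 1 of 10, 0.169) and glycolysis (1 and 9 of 24, 0.173). The same held for neutrophil markers (0 and 1 of 36, 0.276), lymphocyte, monocyte and eosinophil markers (0 and 5 of 13, 0.377), erythrocyte and platelet markers (0 and 4 of 13, 0.525) and epithelial markers (2 and 9 of 20, 0.673). Chloride secretion (1 and 5 of 22, 0.914), NRF2 targets (5 and 10 of 28, 0.917) and the respiratory chain (2 and 2 of 25, 0.972) complete the set. The chloride channel CFTR differed by -1.82 ± 0.22. Without direct replicate 1 with neutrophils the neutrophil markers passed at the preset correlation (median 1.27, adjusted p = 3.05e-07). Without direct replicate 1 lacking neutrophils metallothioneins did (0.76, adjusted p = 0.0431). Barrier-protective HIF genes passed without direct replicate 1 or 3 lacking neutrophils (adjusted p = 0.0453 and 0.0451) and without indirect replicate 2 or 3 lacking them (adjusted p = 0.0490 and 0.0437). Adjusted over the list alone, the counts differed for 10 lists: 17 and 11 for HIF-1 targets, 14 and 2 for EGFR ligands, 1 and 0 for metallothioneins, 2 and 16 for heat shock, 18 and 1 for interferon-stimulated genes, 1 and 18 for cholesterol synthesis, 3 and 13 for the cell cycle, 0 and 0 for the respiratory chain and for neutrophil markers, and 1 and 4 for chloride secretion. Signs of median, mean and test differed for the respiratory chain and chloride secretion.

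**Figure D3:**
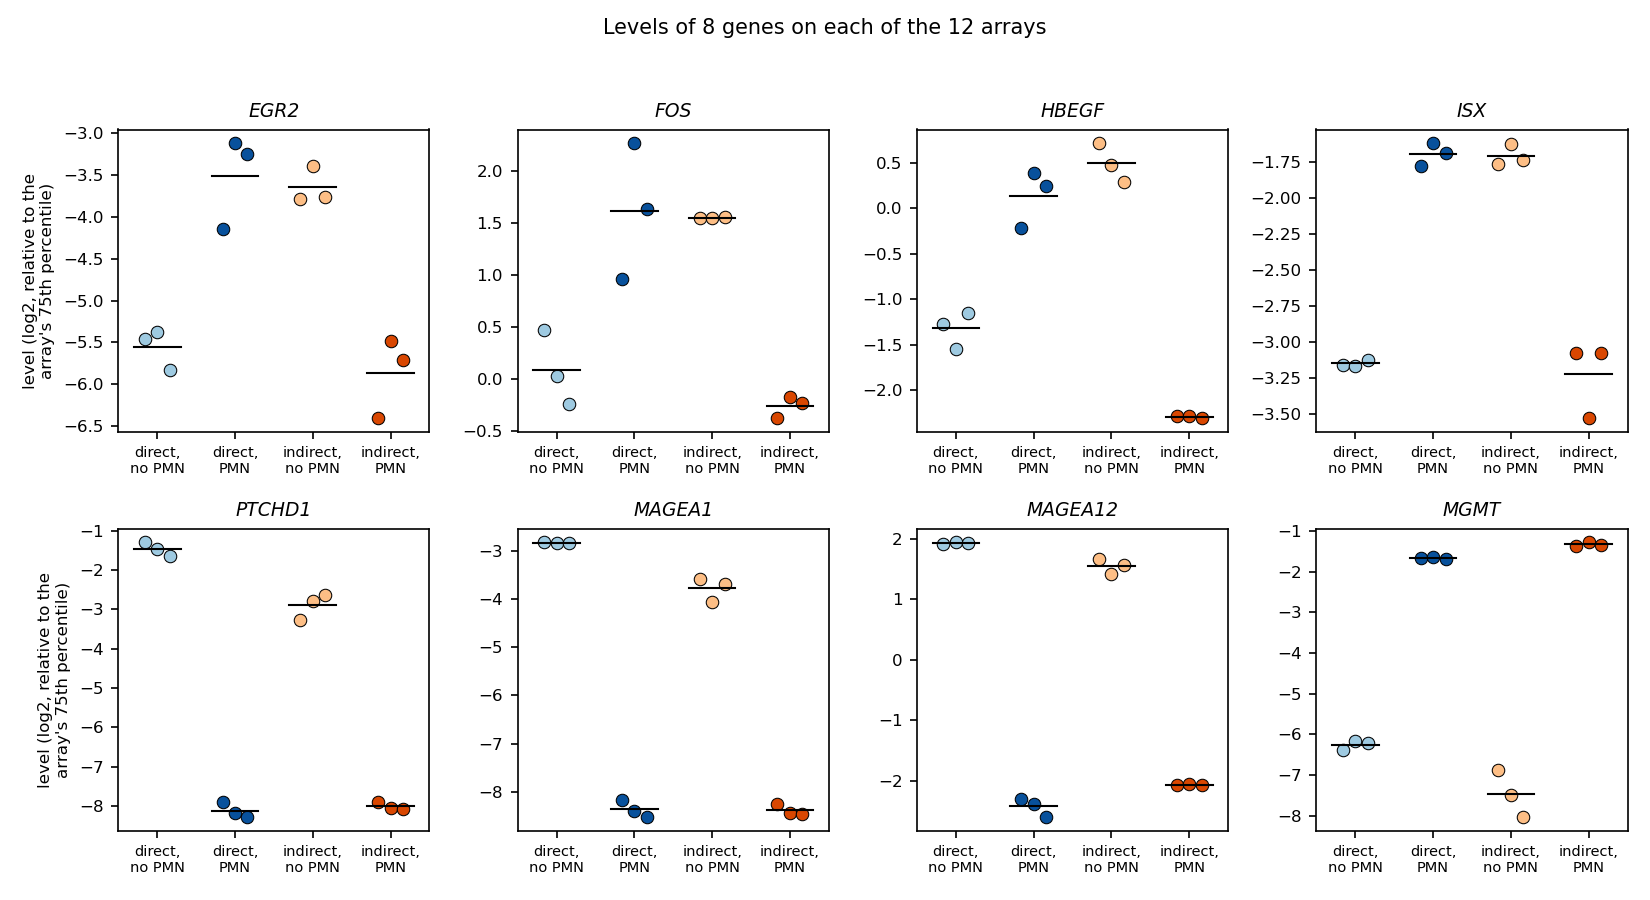
Level of 8 genes on each of the 12 arrays, in log2 units relative to the array's 75th percentile; points are arrays and lines are group means. EGR2, FOS, HBEGF and ISX changed in opposite directions in the 2 models, while PTCHD1, MAGEA1 and MAGEA12 were lower and MGMT was higher with neutrophils in both.

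Without neutrophils the 2 models differ, per the labels, in handling: direct cultures rested in complete medium and indirect ones received a supernatant. All 6 lowest genes of this comparison were metallothioneins, MT1E (log2 -2.66 ± 0.41), MT1M, MT1G, MT1H, MT1X and MT1F (-2.44 ± 0.37), which were lower in the direct than in the indirect cultures (n = 3 and 3 arrays). The highest were the vasoactive peptide gene EDN2 (2.69 ± 0.24), the oxygen sensor gene EGLN3 (2.38 ± 0.13), ZNF114, ANGPTL4, HSD3B1 and SLC16A14. These arrays were scanned on the same day but on different slides.

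In this comparison 6088 genes were higher and 3472 lower in direct than in indirect cultures without neutrophils, of which 520 and 262 had a log2 change of at least 1. With normexp as planned 1647 were higher and 1180 lower. The median of all genes was 0.09 with the main scaling and -0.02 with median centring, and the share of called genes that were higher was 63.7%, 52.4% with quantile normalisation, 45.0% with median centring and 69.0% with normexp fitted without control spots. Of 22 heat shock genes 0 were higher and 17 lower (median -0.62, adjusted p = 4.59e-12, and adjusted p = 0.104 with an estimated correlation), with DNAJB4 at -2.18 ± 0.19. Of 26 unfolded protein response and ATF4 targets 1 was higher and 19 lower (-0.45, adjusted p = 1.34e-09), which held with an estimated correlation (adjusted p = 0.00211). Of 10 metallothioneins 0 were higher and 9 lower (-2.45, adjusted p = 1.13e-06, and adjusted p = 0.349 with an estimated correlation). Glycolysis had 16 higher and 0 lower of 24 (0.37, adjusted p = 5.51e-05, and adjusted p = 0.104 with an estimated correlation), with the glucose transporter SLC2A1 at 1.48 ± 0.17. Cholesterol synthesis had 16 and 0 of 22 (0.52, adjusted p = 5.51e-05, and adjusted p = 0.349 with an estimated correlation), with SQLE at 1.04 ± 0.13. Interferon-stimulated genes had 0 and 13 of 26 (-0.31, adjusted p = 0.000217, and adjusted p = 0.497 with an estimated correlation).

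EGFR ligands and MAPK feedback had 2 higher and 7 lower of 20 in direct cultures without neutrophils (-0.26, adjusted p = 0.00198, and adjusted p = 0.392 with an estimated correlation), with HBEGF at -1.82 ± 0.16. Apical junctions had 3 and 9 of 26 (-0.12, adjusted p = 0.00693, and adjusted p = 0.409 with an estimated correlation), a call that ended without indirect replicate 2 lacking neutrophils (adjusted p = 0.0513). For p53 targets the counts were 0 and 5 of 17 (-0.09, adjusted p = 0.0210, and adjusted p = 0.237 with an estimated correlation), and without direct replicate 2 lacking neutrophils the adjusted p was 0.0529. Immediate early genes had 6 and 11 of 37 (-0.14, adjusted p = 0.0452, and adjusted p = 0.788 with an estimated correlation). Their call ended without direct replicate 2 lacking neutrophils (adjusted p = 0.165), each of indirect replicates 1, 2 and 3 lacking them (adjusted p = 0.0570, 0.0661 and 0.0635) or indirect replicate 2 with them (adjusted p = 0.0518). The call for immediate early genes ended too with median centring (adjusted p = 0.132), quantile normalisation (adjusted p = 0.167), probes well above background on all 12 arrays (adjusted p = 0.0809) and the replicate number as a block (adjusted p = 0.0520). The lists that did not pass were epithelial markers (9 and 0 of 20, 0.0761), NRF2 targets (3 and 6 of 28, 0.0958), barrier-protective HIF genes (2 and 4 of 10, 0.211), NF-kB genes (2 and 5 of 39, 0.211) and lymphocyte, monocyte and eosinophil markers (6 and 1 of 13, 0.211). Cell cycle (11 and 4 of 27, 0.335), cAMP targets (1 and 2 of 14, 0.365), mucins (4 and 2 of 26, 0.443), the respiratory chain (0 and 0 of 25, 0.475) and erythrocyte and platelet markers (3 and 2 of 13, 0.653) did not either. Nor did chloride secretion (5 and 1 of 22, 0.691), neutrophil markers (3 and 0 of 36, 0.812) and HIF-1 targets (10 and 9 of 33, 0.832). Epithelial markers passed without indirect replicate 3 lacking neutrophils (adjusted p = 0.0234). Adjusted over the list alone the counts differed for HIF-1 targets (11 and 9), glycolysis (18 and 0), NF-kB genes (1 and 4), cAMP targets (0 and 0), heat shock (0 and 20), the cell cycle (12 and 4), neutrophil markers (0 and 0) and lymphocyte, monocyte and eosinophil markers (7 and 1). Signs of median, mean and test differed for NF-kB genes, cAMP targets, mucins and the respiratory chain.

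With neutrophils the direct and the indirect cultures were also scanned on 1 day, and they were compared after the scan days had been seen. HOXC8, a homeobox gene, was at least 4.21-fold higher (log2 3.86 ± 0.26, n = 3 and 3 arrays), followed by TCIM, ADM2, EGR4, PDE9A and SYNE3, and the glutamate receptor gene GRIA3 was at least 7.01-fold lower, followed by STK33, CYP1A1, MT1JP, PRKCQ and RNF182. In all 5054 genes were higher and 6292 lower, 830 and 721 with a log2 change of at least 1. With normexp as planned 2483 were higher and 2494 lower, and with median centring 4708 and 6726. Of 37 immediate early genes 33 were higher and 2 lower (median 1.25, adjusted p = 5.18e-12, and adjusted p = 0.291 with an estimated correlation), with ATF3 at 2.58 ± 0.17. Of 22 heat shock genes 1 was higher and 20 lower (-1.12, adjusted p = 9.28e-11, and adjusted p = 0.145 with an estimated correlation), with HSPA1A at -2.31 ± 0.13. Of 26 unfolded protein response and ATF4 targets 21 were higher and 0 lower (0.69, adjusted p = 1.21e-10), which held with an estimated correlation (adjusted p = 0.00153). Of 33 HIF-1 and hypoxia targets 16 were higher and 5 lower (0.27, adjusted p = 0.00230, and adjusted p = 0.490 with an estimated correlation), with BNIP3L at 1.33 ± 0.11.

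Other lists passed in this comparison without holding under an estimated correlation. EGFR ligands and MAPK feedback had 14 higher and 2 lower of 20 (0.92, adjusted p = 0.000109, and adjusted p = 0.325 with an estimated correlation). For p53 targets the counts were 9 and 1 of 17 (0.77, adjusted p = 0.000176, and adjusted p = 0.0615 with an estimated correlation). Apical junctions had 17 and 1 of 26 (0.36, adjusted p = 0.000567, and adjusted p = 0.335 with an estimated correlation) and cAMP targets 9 and 1 of 14 (1.31, adjusted p = 0.000614, and adjusted p = 0.291 with an estimated correlation). Interferon-stimulated genes had 13 and 2 of 26 (0.36, adjusted p = 0.00352, and adjusted p = 0.563 with an estimated correlation), with OASL at 1.98 ± 0.15. NF-kB and cytokine genes had 15 and 3 of 39 (0.88, adjusted p = 0.00576, and adjusted p = 0.580 with an estimated correlation), a call that ended without direct replicate 2 with neutrophils (adjusted p = 0.0695). Metallothioneins had 1 and 9 of 10 (-2.04, adjusted p = 0.00887, and adjusted p = 0.563 with an estimated correlation), and the cell cycle 2 and 15 of 27 (-0.33, adjusted p = 0.0105, and adjusted p = 0.553 with an estimated correlation). Normexp ended the calls for HIF-1 targets, apical junctions and interferon-stimulated genes with neutrophils (adjusted p = 0.153, 0.0553 and 0.0675).

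The lists that did not pass with neutrophils were glycolysis (10 higher and 3 lower of 24, 0.0648), neutrophil markers (4 and 0 of 36, 0.0901), cholesterol synthesis (2 and 8 of 22, 0.0933) and mucins (4 and 2 of 26, 0.156). Barrier-protective HIF genes (3 and 0 of 10, 0.165), NRF2 targets (5 and 12 of 28, 0.197), epithelial markers (7 and 2 of 20, 0.353) and chloride secretion (5 and 4 of 22, 0.353) did not either. Nor did erythrocyte and platelet markers (0 and 5 of 13, 0.463), the respiratory chain (3 and 6 of 25, 0.509) and lymphocyte, monocyte and eosinophil markers (2 and 2 of 13, 0.871). Without direct replicate 1 with neutrophils, neutrophil markers passed at the preset correlation (median 1.44, adjusted p = 1.38e-10), as did glycolysis (adjusted p = 0.0330). Glycolysis also passed without indirect replicate 2 with neutrophils (adjusted p = 0.0482) or indirect replicate 1 lacking them (adjusted p = 0.0471), and cholesterol synthesis without indirect replicate 2 with neutrophils (adjusted p = 0.0482). Adjusted over the list alone the counts differed for glycolysis (11 and 3), barrier-protective HIF genes (1 and 0), immediate early genes (34 and 3), EGFR ligands (15 and 2), NRF2 targets (5 and 13), unfolded protein response and ATF4 targets (22 and 1), the respiratory chain (3 and 3), mucins (2 and 2), chloride secretion (4 and 3), neutrophil markers (0 and 0) and lymphocyte, monocyte and eosinophil markers (1 and 1). Signs of median, mean and test differed for epithelial markers and for lymphocyte, monocyte and eosinophil markers.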

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

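The tests of scan day and of neutrophil RNA in the indirect cultures were chosen only after the result was seen, as was the contrast of both models with neutrophils.

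Many genes changed alike in the direct and indirect neutrophil contrasts (r = 0.587 across genes), among them genes such as PTCHD1, MAGEA1 and MGMT that were well above background on all arrays of 1 label and on none of the other. Scaling by the 75th percentile is argued against as the cause, since the correlation was 0.589 under quantile normalisation, and under median centring, where it is fixed by construction, 7560 genes still had calls of the same direction. A difference in T84 stock between the arrays with and without neutrophils may contribute: over 270 autosomal regions of 10 Mb with at least 20 genes, the SD of region medians of the mean effect was 1.95 times its permuted median (0.149 against 0.0768, p = 0.001, the smallest that 1000 permutations can give). The ratio was 1.85 for the direct effect, 1.66 for the indirect effect, 1.48 for the models without neutrophils and 1.22 for the difference, and genes that lie together can also share regulation, so the test does not single out copy number. Chromosome X was not part of this test, although the probes of PTCHD1 and MAGEA12, among the lowest genes of the direct model, lie on it. Scan day stays open, since 0 scan days hold both labels and the effects cannot be told apart, and so does a like response to neutrophils and to their products, which was not tested apart from these.

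The slide identifiers in the headers of 6 arrays differ from those in their names, as if the direct group with neutrophils and the indirect group without them had been exchanged. An exchange is argued against: neutrophil markers were higher in the arrays labelled direct with neutrophils than in those labelled indirect without them (median difference 2.31, 27 higher and 1 lower of 36, p = 0.000572, and p = 0.450 with an estimated correlation). Replicates 2 and 3 carry this difference, since the median marker level of direct replicate 1 with neutrophils (-4.42) lies close to those of the indirect arrays without them (-5.00 to -4.90), so for that array the values do not settle it. With the labels exchanged the correlation between the effects would be 0.0752. Which identifier is right stays open, and no biological explanation was tested.

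Neutrophil markers were higher in the indirect cultures given the supernatant of migrated neutrophils, although cells had been pelleted and the supernatants passed through a 0.2 µm filter, which should remove whole cells. RNA of neutrophils in these cultures is a candidate explanation: over the 36 markers the indirect effect correlated with the direct effect computed without direct replicate 1 (r = 0.928, rho = 0.886, permutation p = 1e-05, the smallest that the permutations can give). The permutation treated the markers as independent, while the estimated correlation between them was 0.70. Over all genes the 2 effects already correlated at r = 0.587, so the p-value does not measure how particular the markers are. SRGN, an abundant neutrophil transcript, was well above background on 3 arrays of these cultures and on 0 of those without neutrophils, and at least 52.2-fold higher. Between 23 and 25 of the 36 markers were also well above background on arrays of the indirect model without neutrophils. Whether such RNA came through the filter, or whether the epithelial cells made it, was not tested.

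The effect of neutrophils differed between the models in 3788 genes that were higher and 6595 that were lower in the direct model, by the test of the difference, and the excess of lower effects depends on the scaling. Of 100 splits of the arrays within each model only the real one, 1 split, gave as many genes (10383 against at most 7024 in the others). Such splits also break up the neutrophil effect within a model, so they are not a null of equal effects in both models. They cannot tell whether the difference arose by chance. The split with 7024 exchanged 1 array with and 1 array without neutrophils in the direct model alone, so it keeps most of the real grouping. The log2 differences were 4.27 for EGR2, 4.24 for HBEGF, 3.47 for JDP2, 3.47 for KLF2 (a second probe at -0.27), 3.40 for SESN2 and 3.34 for FOS. They were -3.66 for CYP1A1, -3.55 for RNF182, -3.28 for AKAP7, -3.22 for GRIA3, -3.10 for STK33 and -3.10 for HAS1. These are fitted values without a bound, although GRIA3 and STK33 were not well above background on any array of at least 1 group. GRIA3 missed the threshold without direct replicate 3 with neutrophils (-2.98), direct replicate 1 lacking them (-2.99) or indirect replicate 2 lacking them (-2.97), and RNF182 (0.10) and HAS1 (0.0616) turned positive with normexp.

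Gene lists that passed the test of the difference had median differences of 1.45 for immediate early genes, 1.15 for cAMP and CREB targets, 1.15 for EGFR ligands and MAPK feedback and 1.13 for unfolded protein response and ATF4 targets. The values were 0.91 for p53 targets, 0.79 for NF-kB and cytokine response, 0.66 for interferon-stimulated genes, 0.47 for apical junctions and 0.35 for HIF-1 and hypoxia targets. They were -0.36 for the cell cycle, -0.52 for heat shock and -0.74 for cholesterol synthesis. Only the calls for unfolded protein response and ATF4 targets (adjusted p = 0.000370) and for p53 targets (adjusted p = 0.0263) held with an estimated correlation. The calls for the cell cycle and for HIF-1 targets ended when single arrays were left out, with adjusted p of 0.0530 and 0.0580, and of 0.0529, 0.0742 and 0.0632, and that for HIF-1 targets also ended with normexp (0.392), quantile normalisation (0.0762) and median centring (0.0562).

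For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes as the real one. The real split called 13587 genes in the direct model, 15236 in the indirect model, 9560 without neutrophils and 11346 with them. The highest of the other splits called 0, 0, 2 and 0.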

How the results depend on the processing

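Fits without control spots in normexp and with exchanged labels were chosen after seeing the data. Over all settings but the set tests, 2537 values of gene lists stayed on their side of the threshold, 43 were weaker and 42 stronger. Of single genes 8871 stayed, 308 were weaker, 3 stronger and 15 reversed. Direction was compared only for results called in the main fit. No list that passed both in the main fit and in a setting changed direction there. With an estimated correlation 65 list results stayed on their side of the threshold and 50 were weaker, and with fry 81 stayed, 29 were stronger and 5 weaker.

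Planned normexp gave 4577 genes higher and 3034 lower in the direct model, 4882 and 3159 in the indirect model, 1664 and 2097 for the difference, 1647 and 1180 without neutrophils, and 2483 and 2494 with them. It gave 3655 genes of like and 632 of opposite direction in both models and a correlation of 0.575. On direct replicate 2 with neutrophils 8 dark control spots set the fitted background to -337 intensity units, against -2.44 without control spots, and without them no count moved by over 1.5 times. Under it these log2 values reversed: CCNE2 0.40, CLC 0.71, LCK 0.42, MS4A7 0.71 and PF4 0.45 in the direct model, and AHSP 0.0494, CD2 0.19, GP1BB 0.24, HAS1 0.0616, IL1RN 0.0234, MS4A7 0.34, PRF1 0.29 and RNF182 0.10 in the difference. Without control spots the correlation was still lower (0.565), and only CLC (0.0263) and MS4A7 (0.0366) were reversed, in the direct model; the cause was not tested.

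An adjusted p under 0.01 gave 1102 genes of opposite direction and 4396 with a lower effect in the direct model, and 3493 higher and 2190 lower without neutrophils, since fewer genes pass it. Median centring gave 4043 genes higher in the direct model without neutrophils, since it moves the median of that contrast from 0.09 to -0.02. The correlation was 0.522 without a filter on dim probes and 0.539 with probes above background on all 12 arrays; the cause was not tested. Exchanged labels gave a correlation of 0.0752, 2687 genes of like direction, 6876 lower without neutrophils, 3472 higher in the direct and 6292 higher in the indirect model, and 9468 lower in direct than in indirect cultures with neutrophils, as the other groups then enter.

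Leaving out 1 array at a time gave correlations of 0.566 to 0.595, 6788 to 7918 genes of like and 1703 to 2216 of opposite direction. It gave 5945 to 7094 higher and 5764 to 6911 lower in the direct model, 8486 to 9534 and 5328 to 5787 in the indirect model, 3322 to 3892 and 5742 to 6913 for the difference, 4713 to 6211 and 2733 to 3466 without neutrophils, and 4279 to 5336 and 5119 to 6591 with them.

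Whether the replicate numbers pair the arrays stays open. Deviations of same-numbered arrays from their group means correlated at -0.11 to 0.23, with 4 of 18 pairs over 0.1. By these deviations 7 of 12 arrays were best matched by their own number, which was not set against chance. With the number as a block the counts were 6844 and 6663 in the direct model, 9445 and 5753 in the indirect model, 3765 and 6532 for the difference, 6081 and 3431 without neutrophils and 5068 and 6224 with them. A fit with slide or scan day as a block was not run, since no slide or day holds both labels. Genes dim in a group have only a bound there.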

Other observations

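Chromosome regions also moved with the label for neutrophils. The regions named here were chosen after their values were seen, from 270 autosomal regions of 10 Mb on build hg17. On chromosome 1, 57 genes between 90 and 100 Mb had a median log2 change of 0.50 in the direct and 0.63 in the indirect model, and -0.02 between the models without neutrophils. On chromosome 16, 38 genes between 40 and 50 Mb had medians of 0.53 and 0.53, and -0.01 without neutrophils. On chromosome 6, 43 genes between 100 and 110 Mb had medians of -0.24 and -0.23, and 0.02 without neutrophils, and 74.4% of them were lower in the mean of both effects. Across the regions the medians of the direct and indirect effects correlated (r = 0.655), where regions are not independent replicates.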
